A study of Rattus norvegicus and Homo sapiens with 6 samples.

How the data were processed

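Gene expression was measured on 1-colour Agilent arrays in a pair of lung cell lines. NR8383 is a rat alveolar macrophage line and A549 is a human alveolar epithelial line. Per the labels, cells received 1 of 2 kinds of single-wall carbon nanotubes, named CNT-1 and CNT-2, at 0.1 mg/mL for 24 hours in a solution of bovine serum albumin at 1 mg/mL, or that solution alone (control). The title of the series names residual metals in the nanotubes, but the labels do not say which kind holds which metals. Each of the 6 groups had 4 arrays, which gives 12 arrays per cell line and 24 arrays in all. The series text gives n = 4 per group and does not say whether the 4 arrays came from separately treated cultures, so every p-value measures spread between arrays that may be technical. The 4 arrays of each group lay on 1 slide and were scanned together, so slide and group cannot be told apart.

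Per the labels, RNA was labelled with Cy3 and hybridised to the rat or human 44K design, and the authors made the scanner files with Agilent Feature Extraction 10.7.3.1. The values taken from the deposited scanner files are spot intensities (unit: intensity) that the software had corrected for background and spatial trend within each array, with no normalization between arrays and with a surrogate value where a spot was not above its error. The raw mean signal and the local background of each spot in these deposited files are intensities as well. In the deposited value table, which has a single column per group, the values are log2 values relative to the control. Set against the scanner files, these log2 values follow the log2 intensity minus the 75th percentile of the array, minus the median of the 4 control arrays for each probe, averaged over the arrays of the group (Pearson r across probes at least 0.9997, probes not being independent). The NR8383 CNT-1 column is the exception, since it follows the mean of arrays 2 to 4 (r = 0.9998) more closely than the mean of all 4 arrays (r = 0.932). The deposited value table has no replicates and gives no p-value. It was used for this check and as an alternative source of the values of named genes.

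The values reported here start from the spot intensities. The log2 intensity of each spot was centred on the 75th percentile of its array, spots marked by the software as non-uniform or outlying were set to missing, and spots of 1 probe were averaged. Probes well above background on all 4 arrays of at least 1 group were kept, which left 22583 of 41012 probes in NR8383 and 24836 of 41000 probes in A549. Each gene name was represented by its brightest kept probe, giving 18763 and 17658 gene names, of which 9375 and 12317 were plain gene symbols and the others were accession, predicted or numbered locus names. A level is this centred log2 value, and a difference is the difference of the group means of 4 arrays with its standard error (SE). Positions are those of the probe in the array files, on rn4 for rat and hg19 for human. A gene counted as well above background in a group only on the arrays where the software marked its probe so. Where a gene was not well above background on any array of 1 group, the fold is given as a bound, "at least" so much, set by the level that the background allowed.

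Depth on arrays is signal over background. The 75th percentile of the intensity was 636 to 782 on the NR8383 arrays and 603 to 1085 on the A549 arrays, and no spot was saturated. The number of arrays limits the precision. The median SD between arrays of a group was 0.09 log2 units in NR8383 and 0.15 in A549.

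Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 model for the 12 arrays of a cell line), with the data.table package (version 1.17.8) for reading. P-values were two-sided and adjusted by Benjamini and Hochberg over all gene names of a comparison. A gene was called at an adjusted p under 0.05, and counted as at least 2-fold at an absolute log2 difference of at least 1. The comparisons were CNT-1 with control, CNT-2 with control and CNT-2 with CNT-1 in each cell line. A further test set the response of A549 minus the response of NR8383 for the 7486 gene symbols measured on both arrays, which were matched by symbol in upper case and not by orthology. Both nanotube groups shared the 4 control arrays, so calls common to both were set against chance, against simulated noise with the same sharing, and against splits of the controls in which each nanotube had its own 2 control arrays. For a panel of genes an exact permutation test (two-sided, 4 arrays against 4) stands beside the limma result, and the smallest p it can give is 0.0286.

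Fixed before the data were examined were 35 gene lists, covering NRF2 antioxidant targets, metallothioneins, iron handling, inflammatory cytokines, chemokines, NF-kB targets, interferon-stimulated genes, inflammasome, macrophage receptors, lysosome, autophagy, unfolded protein response, heat shock, hypoxia, p53 targets, mitosis, DNA replication, cholesterol synthesis, sterol efflux, fatty acid synthesis, matrix and fibrosis, matrix proteases, immediate early genes, aryl hydrocarbon receptor targets, glycolysis, oxidative phosphorylation, apoptosis, proteasome, ribosomal proteins, housekeeping genes, and markers of alveolar epithelium, macrophages and leukocytes, lymphocytes, fibroblasts and endothelium. Of 777 rat and 787 human list genes, 606 and 632 were measured. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, which compares the list with all other genes, and p-values were adjusted over the lists. An estimated correlation and fry, which tests whether the list's genes moved on balance without comparing them with other genes, were run beside it.

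The rule for named genes, also fixed before the data were examined, had 3 parts. Part 1 took, for each comparison, up to 10 plain symbols with the largest rise and up to 10 with the largest fall among genes called at 2-fold or more whose arrays did not overlap between the groups, and the text gives those at the top of that order. Part 2 was a panel named in every comparison where measured (HMOX1, NQO1, GCLM, SRXN1, MT2A, TFRC, FTH1, CCL2, IL1B, TNF, CXCL8 in human and Cxcl2 in rat, PTGS2, HMGCS1, DDIT3 and CDKN1A). Part 3 took the 4 called members with the largest change of each list that passed camera. Other genes are named as chosen after their values were seen. Some genes that the rule takes are not reported here, although they were tested and count in the lists.

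Alternatives tried were quantile normalization, centring on the median, normexp background correction (offset 50), no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, only the 8 arrays compared, an intensity trend, array quality weights, the array number as a block, and leaving out each array. Centring on the spike-in probes, counting plain symbols only, and leaving out arrays in the list tests and for the difference between cell lines were added after the data were seen. For named genes only, the deposited value table also counted among the alternatives, and having no p-value it could not lose a call. A slide block could not be fitted. The fit was tested on simulated data in which 200 genes were given known differences. At a true log2 difference of 1 it recovered 85.1 to 94.0% of them, and at 0.5 it recovered 47.8 to 76.1%, with 2.34 to 7.78% false calls, over the comparisons within a cell line. The simulated noise was independent between genes and held no slide effect, so these rates do not cover false calls that slides could cause. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.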

Results

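Transcript levels were measured on 24 arrays in 6 groups of 4 arrays. NR8383 rat alveolar macrophages and A549 human alveolar epithelial cells were each cultured for 24 hours with CNT-1, with CNT-2 or with the albumin solution alone. CNT-1 and CNT-2 are kinds of single-wall carbon nanotubes, and the title of the series asks how the metals left in such nanotubes affect the response of the cells. The NR8383 labels call both nanotubes impurity-free and the A549 labels do not, and no label gives the metal content of either kind. The 75th percentile of the spot intensity averaged 671 ± 24.4 (SD, n = 4 arrays) in NR8383 controls, 702 ± 56.2 with CNT-1 and 722 ± 39.8 with CNT-2. In A549 it averaged 991 ± 105 in controls, 971 ± 118 with CNT-1 and 686 ± 67.6 with CNT-2. Between 54.8 and 62.0% of probes were well above background on the NR8383 arrays, and between 57.7 and 66.1% on the A549 arrays.

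Values below are log2 differences ± SE between means of 4 arrays, with p-values adjusted over all genes tested. A gene is said to have risen or fallen only where it was called, and every gene so named had all 4 arrays of 1 group beyond all 4 arrays of the other group, except where stated. The arrays carry probes for E1A spike-in RNA, which is added in known amount and does not depend on the cells. Used here were the 7 such probes that were well above background on all 12 arrays of a cell line. After scaling, these probes differed from control by a log2 value of 0.01 with CNT-1 and 0.00 with CNT-2 in NR8383, and by 0.15 with CNT-1 in A549. In A549 with CNT-2 they lay 1.14 ± 0.58 (SD, n = 4 arrays) above control, with arrays between 0.67 and 1.96. Centring on the spike-in probes instead of the 75th percentile put the median of all genes at −1.09 for A549 CNT-2 against control and at −0.99 for CNT-2 against CNT-1. Changes with CNT-2 in A549 are therefore changes relative to the other genes on the array.

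**Figure D1:**
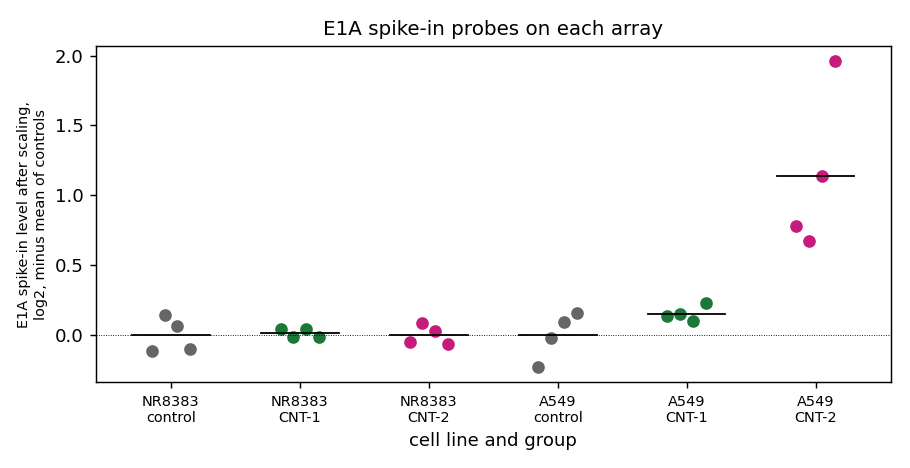
Level of the E1A spike-in probes on each of the 24 arrays (points, log2 after scaling, minus the mean of the controls of the same cell line) by cell line and group, with group means as lines. The 4 arrays of A549 with CNT-2 lay between 0.67 and 1.96, above those of every other group.

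The first comparison asked what CNT-1 did in NR8383 macrophages. Genes of cholesterol synthesis and uptake rose together, genes of the NRF2 antioxidant response rose, and Tfrc, which encodes the transferrin receptor that takes up iron, fell by 1.74 ± 0.06 (adjusted p = 1.04e-07). Star, a carrier of cholesterol into mitochondria, rose by 1.68 ± 0.09 (adjusted p = 6.94e-07; rn4 chromosome 16, 70640879 to 70640938). The cholesterol enzyme Fdft1 rose by 1.40 ± 0.06 (adjusted p = 2.25e-07; chromosome 15, 42436506 to 42436565). The heme oxygenase Hmox1 rose by 0.54 ± 0.04 (adjusted p = 1.01e-05; chromosome 19, 13969336 to 13969395), and the quinone reductase Nqo1 by 0.59 ± 0.05 (adjusted p = 1.58e-05). The inflammatory cytokine Tnf differed by 0.07 ± 0.04 (adjusted p = 0.275) and Il1b by 0.03 ± 0.06 (adjusted p = 0.793), and neither was called.

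Of 25 measured genes of cholesterol synthesis and uptake, 24 rose in NR8383 with CNT-1 and 1 was not called, with the same count adjusted over the list alone, a median of 0.67, and 4 of them at 2-fold or more (camera adjusted p = 3.99e-31, and 0.0093 with an estimated correlation). After Fdft1, its largest rises were Sc5dl (1.21 ± 0.06), Idi1 (1.05 ± 0.05) and Sqle (1.05 ± 0.05), and the panel gene Hmgcs1 rose by 0.86 ± 0.05. Of 22 NRF2 targets, 15 rose and none fell, with the same count adjusted over the list alone and a median of 0.27 (camera adjusted p = 1.07e-10, and 0.00352 with an estimated correlation). Among these, Osgin1 rose by 0.95 ± 0.13, Akr1b8 by 0.67 ± 0.04, the heme transporter Slc48a1 by 0.58 ± 0.04 and Srxn1 by 0.55 ± 0.04. Of 31 proteasome genes, 15 rose (24 adjusted over the list alone), among them Psma1 (0.25), Psmb6 (0.23), Psma3 (0.23) and Psmb1 (0.21), with a camera adjusted p of 3.37e-08, and 0.0093 with an estimated correlation. These 3 lists were the ones of 14 passing camera that also passed with an estimated correlation.

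The other 11 lists that passed camera for CNT-1 in NR8383 (adjusted p from 5.12e-06 to 0.0405) did not pass with an estimated correlation. Of 27 genes of the unfolded protein and integrated stress response, 12 rose (14 rose and 1 fell adjusted over the list alone), led by Ppp1r15a (0.33), Creld2 (0.33), Atf4 (0.30) and Herpud1 (0.29). Its adjusted p was 0.146 with an estimated correlation. Of 32 lysosome genes, 9 rose, among them Atp6v0d2 (0.31), Neu1 (0.30), Mcoln1 (0.25) and Atp6v1c1 (0.24). With an estimated correlation, its adjusted p was 0.146. Of 34 DNA replication genes, 5 rose, among them Rfc4 (0.30), Gins2 (0.27), Rrm2 (0.26) and Pole2 (0.18), and 29 were not called (adjusted p = 0.34 with an estimated correlation). Of 37 ribosomal protein genes, 3 rose, namely Rpl10a (0.22), Rpl4 (0.17) and Rps13 (0.14, a call lost in 14 of 25 alternatives), and none was called adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). Of 20 immediate early genes, which respond first to stimulation, 10 fell (13 adjusted over the list alone), led by Nr4a3 (−1.33), Dusp6 (−0.59), Junb (−0.45) and Egr1 (−0.42). The adjusted p of this list was 0.146 with an estimated correlation. Of 12 genes of matrix proteases and their inhibitors, 5 fell (6 adjusted over the list alone), among them Mmp9 (−1.28 ± 0.07), Mmp2 (−0.69), Mmp7 (−0.26) and Mmp12 (−0.23). Its adjusted p was 0.146 with an estimated correlation. In the hypoxia list of 25 genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with Vegfa at −1.07, Angptl4 at −0.91, Pfkl at −0.48 and Adm at 0.46 (adjusted p = 0.146 with an estimated correlation).

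In NR8383 with CNT-1, 3 of 9 glycolysis genes fell, and they were the lactate transporter Slc16a3 (−1.54 ± 0.06), Tpi1 (−0.27) and Eno2 (−0.22). With an estimated correlation, its adjusted p was 0.239. Of 15 chemokine genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), and the falls were Ccl22 (−0.74), Ccl17 (−0.56), Ccl9 (−0.52) and Ccl4 (−0.46). The adjusted p of this list was 0.34 with an estimated correlation. Of 18 macrophage surface and scavenger receptors, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with the endotoxin co-receptor Cd14 at −1.13 ± 0.15, Itgam at −0.30, Tlr4 at −0.22 and Msr1 at 0.27 (adjusted p = 0.351 with an estimated correlation). Of 23 interferon-stimulated genes, 2 fell, namely Mx2, which was at least 2.06-fold lower, and Ifi35 (−0.14). Its adjusted p was 0.517 with an estimated correlation. The largest falls in this comparison besides Tfrc were Rbpjl (−2.35 ± 0.62), Tcte1 (at least 2.34-fold lower), Ccno (−1.76 ± 0.47), the dicarboxylate carrier Slc13a3 (−1.72 ± 0.07), Vsig8 (−1.70 ± 0.09) and Plac8 (−1.50 ± 0.15). The panel genes Ccl2 (0.16, adjusted p = 0.155), Cxcl2 (−0.23, 0.163), Fth1 (0.13, 0.138), Mt2A (−0.11, 0.224) and Cdkn1a (−0.12, 0.0911) were not called, and Ddit3 rose by 0.15 ± 0.04 (adjusted p = 0.0377), a call lost in 13 of 25 alternatives. Of the 18 iron genes, 4 rose and 2 fell, with a median of 0.06 and a mean of −0.03 (camera adjusted p = 0.531), and 1 of 4 metallothioneins rose (camera adjusted p = 0.562). Inflammatory cytokines and mediators had 1 rise and 4 falls among 11 genes, with a median of 0.03 against a mean of −0.15 (camera adjusted p = 0.201). NF-kB genes had 6 rises and 2 falls among 16 (camera adjusted p = 0.0511), fatty acid synthesis 5 and 1 among 11, matrix and fibrosis genes 0 and 2 among 11, and oxidative phosphorylation 1 and 0 among 29 (0.0739 for each of these 3). Inflammasome genes had 1 rise and 2 falls among 8 (camera adjusted p = 0.116), heat shock proteins 5 and 1 among 17 (0.21), sterol efflux and lipid storage 3 and 5 among 21 (0.252) and autophagy 3 and 0 among 18 (0.37). Mitosis genes had 0 rises and 2 falls among 34, with a median of 0.01 and a mean of −0.01 (camera adjusted p = 0.58), aryl hydrocarbon receptor targets 1 and 0 among 4 (0.644), p53 targets 3 and 1 among 18 (0.67), housekeeping genes 3 and 2 among 15 (0.867) and apoptosis regulators 2 and 1 among 17 (0.945). Markers of alveolar epithelium, macrophages and leukocytes, lymphocytes, fibroblasts and endothelium had at most 2 rises and 4 falls each (camera adjusted p from 0.139 to 0.867).

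In all, 3308 of 18763 genes were called for CNT-1 in NR8383, 2008 higher and 1300 lower, and 85 of them changed by at least 2-fold, 18 higher and 67 lower. The groups did not overlap for 23.4% of genes, where chance gives 2.86%. Leaving out control array 2 lowered the calls to 2186, no filter on dim probes to 1427 and centring on the spike-in probes to 753. Genes at 2-fold or more numbered 14 with normexp background correction and 30 with the stricter filter, in place of 85.

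The same question for CNT-2 in NR8383 gave a larger rise of the cholesterol genes, and the cytokine genes Tnf and Il1b rose. Hmgcs1, the first committed enzyme of the pathway, rose by 2.42 ± 0.05 (adjusted p = 2.07e-10; chromosome 2, 51754420 to 51754478), and Fdft1 by 2.71 ± 0.06 (adjusted p = 2.07e-10). Tnf rose by 0.83 ± 0.04 (adjusted p = 2.19e-07; chromosome 20, 3662706 to 3662765) and Il1b by 0.61 ± 0.06 (adjusted p = 3.18e-05; chromosome 3, 116964716 to 116964775). Tfrc differed by −0.05 ± 0.06 (adjusted p = 0.581) and Nqo1 by −0.01 ± 0.05 (adjusted p = 0.858), and neither was called. Hmox1 rose by 0.25 ± 0.04 (adjusted p = 0.000642).

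With CNT-2 in NR8383, all 25 measured genes of cholesterol synthesis and uptake rose, also when adjusted over the list alone, with a median of 1.70 and 19 at 2-fold or more (camera adjusted p = 1.14e-31, and 0.0206 with an estimated correlation). Besides Fdft1 and Hmgcs1, Sc5dl rose by 2.38 ± 0.06 and Idi1 by 2.27 ± 0.05. This was the only one of 7 lists passing camera that also passed with an estimated correlation. Of 11 fatty acid synthesis genes, 7 rose, among them Fads1 (1.36 ± 0.31), Acss2 (1.29 ± 0.04), Elovl6 (1.12 ± 0.05) and Mid1ip1 (0.69 ± 0.05), with a camera adjusted p of 0.00114, and 0.207 with an estimated correlation. Of 16 NF-kB feedback and target genes, 12 rose (14 adjusted over the list alone), led by Nfkbiz (1.17 ± 0.07), Tnfaip2 (0.87), Birc3 (0.64) and Sod2 (0.52), with a camera adjusted p of 1.62e-06, and 0.147 with an estimated correlation. Of 27 genes of the unfolded protein and integrated stress response, 18 rose, among them Chac1 (0.54), Atf3 (0.50), Ppp1r15a (0.49) and Herpud1 (0.41), with a camera adjusted p of 1.08e-05. With an estimated correlation, its adjusted p was 0.147. Of 32 lysosome genes, 17 rose (19 rose and 1 fell adjusted over the list alone), among them Atp6v0d2 (0.72), Atp6v1h (0.49), Gla (0.33) and Neu1 (0.31), with a camera adjusted p of 0.000654. The adjusted p of this list was 0.107 with an estimated correlation.

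Many cell cycle genes fell in NR8383 with CNT-2. Of 34 DNA replication genes, 18 fell and 3 rose (20 and 3 adjusted over the list alone), with Cdc6 at −0.59 ± 0.05, Gins3 at −0.46, Mcm10 at −0.43 and Chaf1a at −0.39 (camera adjusted p = 0.00103, and 0.252 with an estimated correlation). Of 34 mitosis genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone), with Cenpf at −0.52 and Aspm at −0.45, and with the rises Cks2 (0.50 ± 0.17) and Nusap1 (0.39), with a camera adjusted p of 0.00298, and 0.252 with an estimated correlation. The NRF2 list had 7 rises and 2 falls among 22 genes (camera adjusted p = 0.186), and inflammatory cytokines had 8 rises and 3 falls among 11 (camera adjusted p = 0.116). Iron genes had 5 rises and 2 falls among 18 (camera adjusted p = 0.295), and metallothioneins 1 rise and 2 falls among 4 (camera adjusted p = 0.808). The largest rises outside these lists were Hint3 (2.91 ± 0.47), Zfp36, which encodes a protein that destabilises cytokine transcripts (at least 1.59-fold higher), Rps26 (2.66 ± 0.20), Dhx16 (at least 2.2-fold higher) and Gtse1 (2.59 ± 0.31). The largest falls were Tlr1 (−1.98 ± 0.57), Rbpjl (−1.96 ± 0.62), Slc13a3 (−1.55 ± 0.07), the ubiquitin ligase Mylip (−1.51 ± 0.04), Vsig8 (−1.43 ± 0.09), Mllt4 (−1.40), Pdk4 (−1.29) and Angptl4 (−1.28). Of the panel, Ccl2 rose by 0.36 ± 0.07, Ddit3 by 0.35 ± 0.04, Srxn1 by 0.24 ± 0.04 and Cdkn1a by 0.24 ± 0.04, and Mt2A fell by 0.27 ± 0.06. Cxcl2 (0.27, adjusted p = 0.0621) and Fth1 (0.03, 0.695) were not called.

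Among lists that did not pass for CNT-2 in NR8383, glycolysis had 5 rises and no fall among 9 genes (camera adjusted p = 0.0556), sterol efflux and lipid storage 5 and 8 among 21 (0.116), p53 targets 9 and 4 among 18 (0.138) and chemokines 3 and 2 among 15 (0.342). Inflammasome genes had 1 rise and 4 falls among 8, with a median of −0.19 and a mean of 0.01 (camera adjusted p = 0.342), and the hypoxia list 8 and 5 among 25, with a median of 0.08 and a mean of −0.03 (0.507). Immediate early genes had 4 rises and 8 falls among 20 (camera adjusted p = 0.507), macrophage receptors 6 and 4 among 18 (0.565), interferon-stimulated genes 2 and 2 among 23 (0.786) and autophagy 4 and 4 among 18 (0.703). Proteasome genes had 6 rises and no fall among 31, apoptosis regulators 5 and 2 among 17, aryl hydrocarbon receptor targets 1 and 0 among 4, heat shock proteins 3 and 3 among 17, oxidative phosphorylation 4 and 1 among 29, matrix and fibrosis 1 and 4 among 11, matrix proteases 4 and 2 among 12 and housekeeping genes 5 and 1 among 15 (camera adjusted p from 0.379 to 0.889). Ribosomal protein genes had 3 rises among 37, with a median of −0.01 and a mean of 0.01 (camera adjusted p = 0.808), and the 5 lists of markers of other cell types had at most 3 rises and 2 falls each (0.274 to 0.912).

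For CNT-2 in NR8383, 6929 of 18763 genes were called, 3378 higher and 3551 lower, with 439 higher and 50 lower by at least 2-fold. Of the 439, 359 (81.8%) had no plain gene symbol, against 50.03% of all genes tested. The groups did not overlap for 38.2% of genes, where chance gives 2.86%. With normexp background correction the genes at 2-fold or more numbered 224 in place of 489, and centring on the spike-in probes lowered the calls to 3937.

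**Figure D2:**
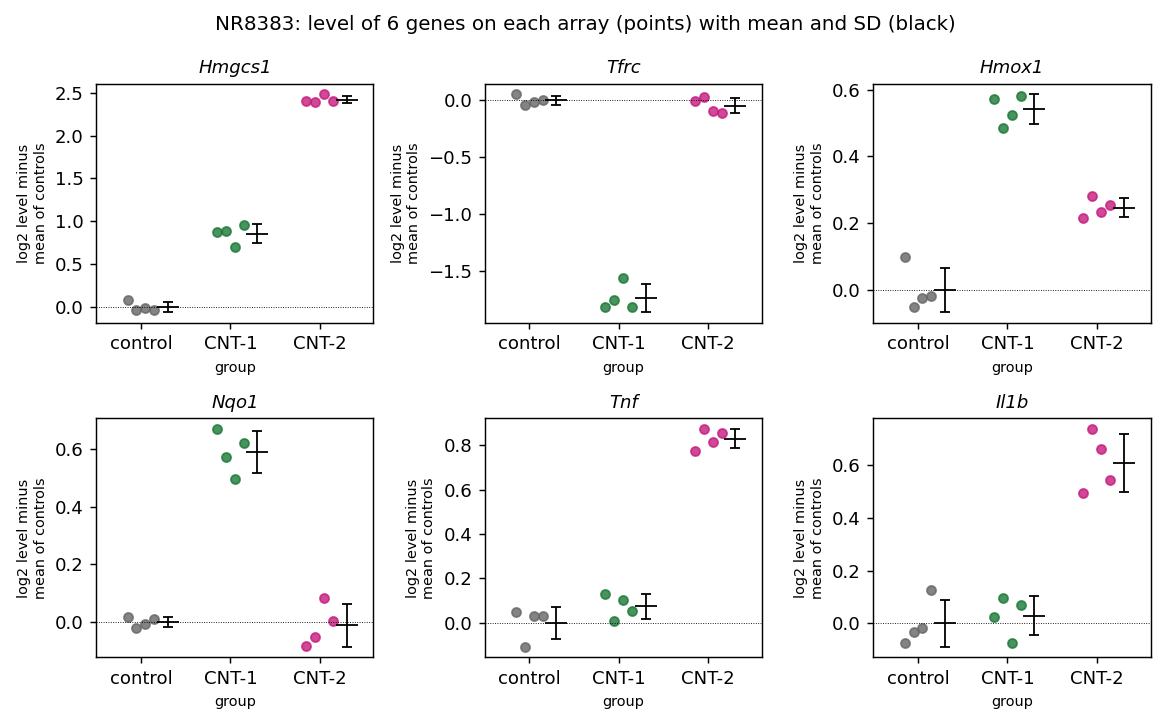
Levels of Hmgcs1, Tfrc, Hmox1, Nqo1, Tnf and Il1b on each NR8383 array (points, log2 level minus the mean of the controls) by group, with mean and SD of 4 arrays in black. Hmgcs1 rose with both nanotubes, to a mean of 0.86 with CNT-1 and 2.42 with CNT-2, Tfrc fell to −1.74 with CNT-1, and Tnf rose to 0.83 with CNT-2.

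Set against each other in NR8383, CNT-2 gave higher cholesterol and inflammatory genes and CNT-1 gave higher NRF2 targets. Hmgcs1 was higher with CNT-2 by 1.56 ± 0.05 (adjusted p = 4.43e-08), Tfrc by 1.70 ± 0.06 (4.43e-08), Tnf by 0.76 ± 0.04 (1.16e-06) and Il1b by 0.58 ± 0.06 (8.54e-05). Nqo1 was lower with CNT-2 by a log2 difference of −0.60 ± 0.05 (adjusted p = 6.57e-06) and Hmox1 by −0.29 ± 0.04 (0.000337). Of 25 cholesterol genes, 24 were higher with CNT-2, 10 of them at 2-fold or more, among them Fdft1 (1.32), Tm7sf2 (1.27) and Idi1 (1.22), with a median of 0.83 (camera adjusted p = 1.25e-29, and 0.0184 with an estimated correlation). Of 22 NRF2 targets, 15 were lower and 1 was higher with CNT-2 (17 and 2 adjusted over the list alone), with Osgin1 at −0.92, Slc48a1 at −0.49 and Gsr at −0.46 (camera adjusted p = 8.49e-06, and 0.0184 with an estimated correlation). Of 34 DNA replication genes, 23 were lower and none was higher (24 adjusted over the list alone), with Cdc6 at −0.59, Gins3 at −0.51, Cdt1 at −0.47 and Rfc5 at −0.37 (camera adjusted p = 6.13e-09, and 0.0408 with an estimated correlation). Of 11 inflammatory cytokines and mediators, 7 were higher and 1 was lower, with Osm at 0.76 and Il1a at 0.64 (camera adjusted p = 0.000129, and 0.0408 with an estimated correlation).

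Another 12 lists passed camera for CNT-2 against CNT-1 in NR8383 (adjusted p from 1.02e-05 to 0.0323) but not with an estimated correlation. Higher with CNT-2 were 11 of 16 NF-kB genes, with 1 lower, led by Cflar (0.54), Tnfaip2 (0.54), Icam1 (0.50) and Bcl3 (0.40). For NF-kB the adjusted p was 0.1 with an estimated correlation. Higher were also 5 of 15 chemokine genes, 6 adjusted over the list alone (Ccl9 0.70, Ccl22 0.67, Ccl4 0.61 and Cxcl2 0.50; 0.105 with an estimated correlation) and 5 of 9 glycolysis genes (Slc16a3 1.95, Eno2 0.45, Tpi1 0.40 and Pfkp 0.30; 0.1 with an estimated correlation). Fatty acid synthesis had 6 of 11 higher and 1 lower, 7 and 1 adjusted over the list alone (Fads1 1.07, Acss2 0.93, Scd 0.73 and Elovl6 0.61). With an estimated correlation, its adjusted p was 0.1. Matrix proteases had 8 of 12 higher (Mmp9 0.47, Mmp7 0.46, Mmp2 0.44 and Mmp14 0.42). The adjusted p of this list was 0.0969 with an estimated correlation. The hypoxia list had 11 of 25 higher and 4 lower (Pfkl 0.80, P4ha1 0.58, Ndrg1 0.56 and Angptl4 −0.37). Its adjusted p was 0.124 with an estimated correlation. Immediate early genes had 7 of 20 higher and 3 lower, 8 and 3 adjusted over the list alone (Egr2 0.73, Ier3 0.58, Maff 0.56 and Jund 0.41). With an estimated correlation, its adjusted p was 0.335. Lysosome genes had 6 of 32 higher and 1 lower (Atp6v0d2 0.41, Atp6v1h 0.28 and Ctsl1 0.24; 0.143 with an estimated correlation), and the unfolded protein list 7 of 27 higher (Atf3 0.40, Ddit4 0.40, Chac1 0.39 and Edem1 0.31; 0.329 with an estimated correlation).

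Of 23 interferon-stimulated genes, 6 were higher and 1 was lower with CNT-2 than with CNT-1 in NR8383 (adjusted p = 0.524 with an estimated correlation). The arrays of the groups overlapped for the 4 with the largest difference, Mx2 (at least 1.9-fold higher), Rsad2 (1.20 ± 0.28), Irf7 (0.90 ± 0.26) and Ifit3 (0.82 ± 0.20). The proteasome list had 15 of 31 lower and 2 higher (Psmd7 −0.25, Psma7 −0.24, Psmd12 −0.18 and Psmd6 0.23). The adjusted p of this list was 0.0969 with an estimated correlation. Mitosis genes had 15 of 34 lower and 2 higher, 20 and 2 adjusted over the list alone (Kif23 −0.34, Aurkb −0.28, Cks2 0.50 and Nusap1 0.27), with an adjusted p of 0.125 with an estimated correlation. The largest differences among plain symbols were Zfp36 (at least 1.86-fold higher with CNT-2), Tob1 (2.37 ± 0.26), Osap (2.34 ± 0.22), Hint3 (2.33 ± 0.47) and, as the single plain symbol lower by at least 2-fold, Star (−1.27 ± 0.09). Of the panel, Cxcl2 (0.50), Cdkn1a (0.36) and Ddit3 (0.20) were higher and Srxn1 (−0.31) was lower with CNT-2. Ccl2 (0.20, adjusted p = 0.0533), Mt2A (−0.16, 0.0669) and Fth1 (−0.10, 0.213) were not called. Macrophage receptors had 7 of 18 higher and 3 lower (camera adjusted p = 0.0614), ribosomal protein genes 1 and 5 of 37 (0.064), sterol efflux 2 and 8 of 21 (0.0648) and p53 targets 8 and 3 of 18 (0.0799). For metallothioneins, iron genes, inflammasome, autophagy, heat shock, matrix, aryl hydrocarbon receptor targets, oxidative phosphorylation, apoptosis, housekeeping genes and the 5 lists of markers of other cell types the camera adjusted p lay between 0.0799 and 0.926. The inflammasome list had a median of −0.09 and a mean of 0.09, and that of macrophages and leukocytes −0.05 and 0.05.

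In all, 5781 of 18763 genes were called for CNT-2 against CNT-1 in NR8383, 2582 higher and 3199 lower with CNT-2, with 343 higher and 4 lower by at least 2-fold, and the groups did not overlap for 33.8% of genes (2.86% by chance). With normexp background correction 118 genes passed at 2-fold or more in place of 347, and spike-in centring lowered the calls to 2096.

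Both nanotube groups in NR8383 shared their controls. Of 18763 genes, 1261 were called higher with both nanotubes (362 by chance), 821 lower with both (246 by chance) and 86 in opposite directions. Giving each nanotube its own 2 control arrays left a median of 1054 shared calls in the same direction over the splits, from 894 to 1247, in place of 2082. The log2 differences correlated across genes with r = 0.54, where noise with shared controls alone gave a mean of 0.50, and genes are not independent replicates. Their covariance was 0.0493, against 0.00912 in that noise.

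CNT-1 in A549 epithelial cells raised CYP1A1, CYP1B1 and TIPARP, targets of the aryl hydrocarbon receptor, which senses polycyclic aromatic compounds, and lowered many transcripts without a gene symbol. The cytochrome P450 gene CYP1A1, not well above background on any control array, rose by at least 3.07-fold (adjusted p = 0.00175; hg19 chromosome 15, 75012562 to 75012621). CYP1B1 of the same family rose by 1.67 ± 0.07 (adjusted p = 1.12e-08; chromosome 2, 38295444 to 38295503). TIPARP, a feedback regulator of the receptor, rose by 1.33 ± 0.06 (adjusted p = 2.73e-08; chromosome 3, 156424310 to 156424369). Of 9 measured receptor targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0103, 0.143 with an estimated correlation and 0.123 with quantile normalization, and from 3.27e-08 to 0.143 over 16 alternatives). The fall was CYP1A2 (−1.56 ± 0.27), and ALDH3A1 (0.59 ± 0.08), UGT1A6 (0.45 ± 0.15) and ALDH1A3 (0.24 ± 0.07), which were chosen after their values were seen, rose.

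Of 27 NRF2 targets in A549 with CNT-1, 12 rose and none fell (13 adjusted over the list alone), led by OSGIN1 (0.56 ± 0.10), TALDO1 (0.47 ± 0.06), GPX2 (0.46 ± 0.08) and GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis (0.40 ± 0.07), with a camera adjusted p of 0.00435, and 0.143 with an estimated correlation. Another probe of TALDO1 was called in the opposite direction. HMOX1 differed by −0.08 ± 0.15 (adjusted p = 0.71) and NQO1 by 0.05 ± 0.06 (0.563), and neither was called, and SRXN1 rose by 0.30 ± 0.07 (0.00573). Of 5 inflammasome genes, 4 rose, namely TXNIP (1.10 ± 0.22), the pore-forming GSDMD (0.58), PYCARD (0.48) and NEK7 (0.32, with overlapping arrays and the call lost in 15 of 25 alternatives), with a camera adjusted p of 0.0294, and 0.143 with an estimated correlation. Of 21 genes of sterol efflux and lipid storage, 10 rose and 1 fell, with the sterol exporter ABCG1 at 1.16 ± 0.15, PLTP at 0.43, ACADVL at 0.39 and the fall PLIN2 at −0.64 (camera adjusted p = 0.0377, and 0.188 with an estimated correlation). Of 26 cholesterol synthesis genes, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with TM7SF2 at 0.70, EBP at 0.45 and MVK at 0.36 (camera adjusted p = 0.0449, and 0.143 with an estimated correlation). HMGCS1 (0.21, adjusted p = 0.152) was not called.

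Further lists that passed camera in A549 with CNT-1 (adjusted p from 0.00112 to 0.0483), none of them with an estimated correlation, held the cell cycle, oxidative phosphorylation, the proteasome and the ribosomal proteins that serve as a sign of RNA quality. Plain symbols as a whole had a median of 0.11 in this comparison and the other names one of −0.13, and camera sets each list against both. Of 37 mitosis genes, 14 rose (16 adjusted over the list alone), among them TPX2 (0.38), CDCA8 (0.33), PTTG1 (0.32) and, with overlapping arrays and the call lost in 14 of 25 alternatives, NEK2 (0.35), with an adjusted p of 0.143 with an estimated correlation. Of 34 DNA replication genes, 9 rose, among them MCM7 (0.39), TK1 (0.36), CHAF1B (0.34) and CDC45 (0.29), with an adjusted p of 0.442 with an estimated correlation. Of 26 p53 targets, 7 rose, among them DDB2 (0.40), FDXR (0.36), RPS27L (0.34) and BTG2 (0.33), with an adjusted p of 0.145 with an estimated correlation. Of 31 proteasome genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with PSMA5 at 0.43, PSMC3 at 0.38, PSMD8 at 0.36 and the fall PSMD3 at −0.43 (adjusted p = 0.437 with an estimated correlation). Of 30 oxidative phosphorylation genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone), with NDUFA2 (0.46), NDUFA1 (0.43), NDUFA4 (0.40) and COX5B (0.38) the largest (adjusted p = 0.437 with an estimated correlation). Of 37 ribosomal protein genes, 16 rose and 1 fell (22 and 1 adjusted over the list alone), with RPS9 at 0.54, RPL3 at 0.53, RPS3 at 0.49 and the fall RPL7 at −1.58 (adjusted p = 0.656 with an estimated correlation).

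The largest falls in A549 with CNT-1 were of PABPC3 (−4.65 ± 0.15, adjusted p = 5.24e-09; chromosome 13, 25672234 to 25672293), NACAP1 (−4.29 ± 0.22), CSNK1A1L (at least 3.97-fold lower), LGI4 (−3.54 ± 0.47), CCDC68 (at least 2.68-fold lower), HMGN1P37 (−3.24 ± 0.13), MARCH4 (at least 3.04-fold lower), RPL23AP32 (−3.09 ± 0.12) and DGKH (−3.05 ± 0.14). NACAP1, HMGN1P37 and RPL23AP32 carry pseudogene names. Of the 959 genes lower by at least 2-fold, 756 (78.8%) had no plain gene symbol, against 30.25% of all genes tested. Besides the receptor targets, AQP3 (1.48 ± 0.20), SERPINB4 (at least 1.25-fold higher), RAB37 (1.31 ± 0.13) and GJB1 (1.25 ± 0.15) had the largest rises. The panel genes TFRC (−0.23, adjusted p = 0.0555), FTH1 (−0.12, 0.284), MT2A (0.01, 0.969), CCL2 (0.07, 0.748), PTGS2 (−0.25, 0.411), DDIT3 (−0.08, 0.651) and CDKN1A (0.14, 0.156) were not called. Iron genes had 4 rises and 2 falls among 19 (camera adjusted p = 0.618), and metallothioneins 1 rise and 1 fall among 13, with a median of 0.01 and a mean of −0.01 (camera adjusted p = 0.923). Interferon-stimulated genes had 6 rises and no fall among 16 (camera adjusted p = 0.0519), fatty acid synthesis 5 and 0 among 14 (0.138), the hypoxia list 6 and 1 among 28 (0.142), unfolded protein genes 6 and 1 among 30 (0.349) and glycolysis 4 and 2 among 12 (0.445). Immediate early genes had 3 rises and 6 falls among 21 (camera adjusted p = 0.246), chemokines 0 and 3 among 9 (0.407), NF-kB genes 1 and 2 among 16 (0.349) and inflammatory cytokines 1 and 2 among 8 (0.736). Lysosome genes had 4 rises and 5 falls among 32, with a median of 0.07 and a test in the direction of lower (camera adjusted p = 0.923), matrix proteases 4 and 2 among 12 with a median of 0.07 and a mean of −0.03 (0.886), and apoptosis regulators 4 and 2 among 18 with a median of 0.03 and a mean of −0.02 (0.821). For macrophage receptors, autophagy, heat shock, matrix, housekeeping genes and markers of other cell types the camera adjusted p lay between 0.232 and 0.917, and fewer than 3 endothelium markers were measured.

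In all, 5767 of 17658 genes were called for CNT-1 in A549, 3246 higher and 2521 lower, with 18 higher and 959 lower by at least 2-fold, and the groups did not overlap for 38.5% of genes (2.86% by chance). Of 34 lists tested, 11 passed camera, 0 did after quantile normalization (the lowest adjusted p was 0.123) and 7 did without CNT-1 array 2. Centring on the spike-in probes left 1273 calls, 11 higher and 1262 lower. With normexp background correction 2979 genes were called and 498 in place of 977 were at 2-fold or more, and with array weights 9285 were called.

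CNT-2 in A549 lowered the aryl hydrocarbon receptor targets and the iron and stress genes TFRC and DDIT3, on arrays whose spike-in level lay 1.14 above control. CYP1B1 fell by 1.11 ± 0.07 (adjusted p = 8.84e-06), ALDH3A1 by 1.01 ± 0.08 (6.38e-05; chromosome 17, 19643743 to 19644417), TIPARP by 0.66 ± 0.06 (0.00013) and ALDH1A3 by 0.37 ± 0.07 (0.00314). Of 9 receptor targets, 5 fell and none rose, with a median of −0.35 (camera adjusted p = 0.0003, and 0.0307 with an estimated correlation), and with spike-in centring the camera adjusted p was 0.0516 (from 3.18e-07 to 0.0516 over 16 alternatives). CYP1A1 was not well above background on any of the 8 arrays compared. TFRC fell by 0.71 ± 0.09 (adjusted p = 0.000489; chromosome 3, 195776593 to 195776652), DDIT3, a mediator of the stress response of the endoplasmic reticulum, by 0.93 ± 0.12 (0.000711), and GCLM by 0.46 ± 0.07 (0.00164).

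Of the 26 genes of the list cholesterol synthesis and uptake in A549 with CNT-2 vs control, 17 rose relative to the other genes and none fell (19 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.19e-06, 0.00562 with an estimated correlation, 0.000915 with spike-in centring, and from 2.12e-08 to 0.00562 over 16 alternatives). Large rises were TM7SF2 (0.71 ± 0.08), ACAT2 (0.60 ± 0.08) and FDPS (0.59 ± 0.08), which all turned negative with spike-in centring (−0.43, −0.54 and −0.55). Of 37 ribosomal protein genes, 17 rose and 1 fell (22 and 1 adjusted over the list alone) on the arrays with the higher spike-in level, with RPL32 (0.42), RPS24 (0.40), RPL28 (0.38) and, with overlapping arrays and with probes called in opposite directions, RPS2 (0.36), all of which turned negative with spike-in centring (−0.72, −0.73, −0.76 and −0.78). The list of cytosolic ribosomal proteins (RNA quality) had a camera adjusted p of 0.0003, and 0.924 with an estimated correlation, 0.252 with spike-in centring and, in the opposite direction, 0.798 with quantile normalization (from 5.58e-05 to 0.924 over 16 alternatives). The largest rises were MAPK4 (1.73 ± 0.10), the gap junction gene GJB1 (1.73 ± 0.15), COX1 (1.59 ± 0.10), H19 (1.57 ± 0.22), ND5 (1.53 ± 0.21) and ND4 (1.45 ± 0.14), all of which stayed higher with spike-in centring, though COX1, H19, ND5 and ND4 were then not called. COX1, ND4 and ND5 are genes of the mitochondrial genome, and the array file places the COX1 probe on chromosome 1. The largest falls were ID4 (−2.17 ± 0.13), FAT4 (at least 1.68-fold lower), PKD1L2 (−1.79 ± 0.39) and TSC22D3 (at least 1.57-fold lower), none of which was called with normexp background correction.

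Of the panel in A549 with CNT-2, HMOX1 (−0.15, adjusted p = 0.495), NQO1 (−0.11, 0.188), SRXN1 (−0.16, 0.0949) and CCL2 (−0.06, 0.763) were not called. MT2A (0.06, adjusted p = 0.807), FTH1 (0.15, 0.184), PTGS2 (0.16, 0.6), HMGCS1 (0.04, 0.804) and CDKN1A (0.14, 0.158) were not called either, and these 5 turned negative with spike-in centring. Chemokines had 5 rises and no fall among 9 (camera adjusted p = 0.074), markers of alveolar epithelium 7 and 1 among 14 (0.074), lysosome genes 2 and 11 among 32 (0.128), the hypoxia list 3 and 7 among 28 (0.128) and interferon-stimulated genes 6 and 3 among 16 (0.185). NRF2 targets had 3 rises and 7 falls among 27 (camera adjusted p = 0.21), iron genes 2 and 4 among 19 with a median of 0.15, a mean of 0.06 and a test in the direction of lower (0.956), and metallothioneins 1 and 0 among 13 (0.494). For the other lists the camera adjusted p lay between 0.14 and 0.956. Among these the median and mean differed in sign for inflammatory cytokines, unfolded protein genes, heat shock, p53, mitosis, sterol efflux and glycolysis, and the test was in the direction of lower with a median of 0.00 or more for matrix, NF-kB and proteasome genes.

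In all, 4811 of 17658 genes were called for CNT-2 in A549, 2699 higher and 2112 lower, with 80 higher and 152 lower by at least 2-fold, and the groups did not overlap for 30.4% of genes (2.86% by chance). Without control array 1 the calls numbered 3080, and without CNT-2 array 4 or array 1 the genes at 2-fold or more numbered 143 or 352 in place of 232. Without CNT-2 array 4, 7 lists passed camera in place of 3, and with spike-in centring 16850 genes were called, 4 higher and 16846 lower. With normexp background correction 1767 genes were called and 57 in place of 232 were at 2-fold or more, and without the filter 3027 were called. The stricter filter left 134 at 2-fold or more.

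**Figure D3:**
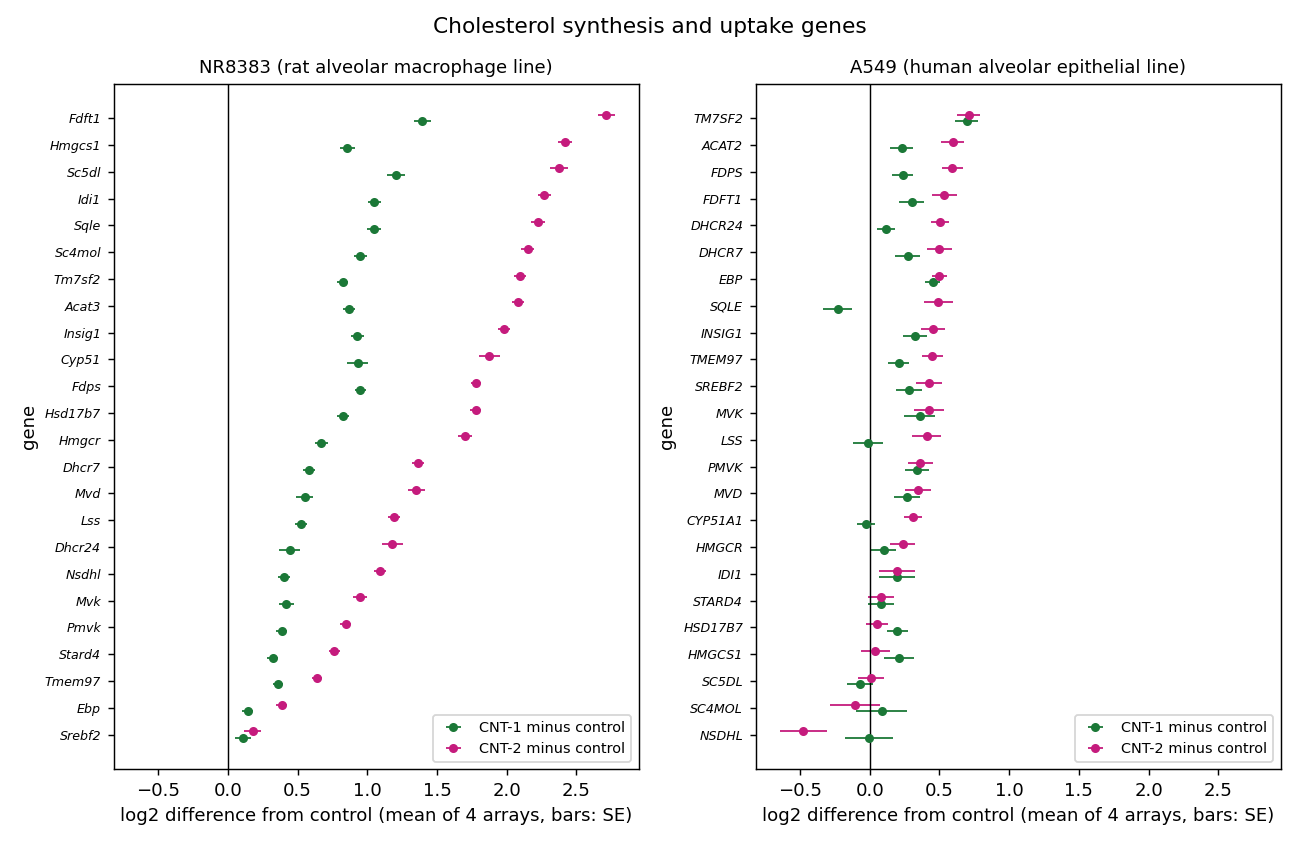
Log2 difference from control (points, mean of 4 arrays against 4, bars SE) of 24 genes of cholesterol synthesis and uptake in each cell line with CNT-1 and CNT-2. Over the whole list in NR8383 the median was 0.67 with CNT-1 and 1.70 with CNT-2, and in A549 it was 0.20 and 0.42, where with spike-in centring the A549 CNT-2 rises of TM7SF2, ACAT2 and FDPS turned negative.

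Set against each other in A549, CNT-2 gave lower CYP1B1, TIPARP, ALDH3A1 and GCLM than CNT-1. CYP1B1 was lower with CNT-2 by −2.78 ± 0.07 (adjusted p = 1.51e-09), TIPARP by −1.99 ± 0.06 (3.41e-09), ALDH3A1 by −1.60 ± 0.08 (4.67e-08), and CYP1A1 was at least 2.31-fold lower. Of 9 receptor targets, 7 were lower and 1 was higher, with a median of −0.76 (camera adjusted p = 0.00183, and 0.0787 with an estimated correlation). Of 27 NRF2 targets, 14 were lower and 1 was higher (15 and 1 adjusted over the list alone), with SLC7A11 at −1.25 ± 0.12, OSGIN1 at −1.15 ± 0.10, GCLM at −0.86 ± 0.07 and PGD at −0.77 ± 0.10 (camera adjusted p = 0.00217, and 0.125 with an estimated correlation). Another probe of SLC7A11 was called in the opposite direction. Of the 28 hypoxia genes, 16 were lower and 3 higher (17 and 3 adjusted over the list alone), with KDM3A at −0.76, PFKFB3 at −0.66, ENO1 at −0.56 and EGLN3 at −0.56 (camera adjusted p = 0.00989, and 0.166 with an estimated correlation), and PFKFB3 was at 0.14 when its probes were averaged. Of 37 mitosis genes, 17 were lower and 3 higher, with TOP2A at −0.9996, AURKB at −0.83, NUF2 at −0.56 and UBE2C at 0.52, the last of which was at −0.47 with spike-in centring (camera adjusted p = 0.0198, and 0.125 with an estimated correlation). Of 31 proteasome genes, 11 were lower and 3 higher, with PSMC3 at −0.95, PSMA5 at −0.57, PSMA7 at −0.55 and PSMD3 at 0.71, which was at −0.27 with spike-in centring and had probes called in opposite directions (camera adjusted p = 0.0316, and 0.578 with an estimated correlation). Of 9 chemokines, 5 were higher and none was lower (6 and 0 adjusted over the list alone), with CCL24 at 1.03, and CX3CL1, CXCL3 and CXCL16 at 0.80, 0.69 and 0.30, which turned negative with spike-in centring at −0.18, −0.30 and −0.68 (camera adjusted p = 0.0258, and 0.271 with an estimated correlation).

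The genes lowest with CNT-1 in A549 were among the highest with CNT-2 against CNT-1, a comparison that uses the same CNT-1 arrays, with PABPC3 at 4.60 ± 0.15, NACAP1 at 4.24 ± 0.22, LGI4 at 3.57 ± 0.47, TSPAN32 at least 3.24-fold higher, HMGN1P37 at 3.26 ± 0.13 and RPL23AP32 at 3.09 ± 0.12. Besides the receptor targets, the largest falls were FAT4 (at least 2.61-fold lower), the water channel AQP3 (−2.09 ± 0.20) and the sterol exporter ABCA1 (at least 1.55-fold lower). Of the panel, SRXN1 (−0.46), TFRC (−0.48), DDIT3 (−0.85) and NQO1 (−0.15, a call lost in 16 of 25 alternatives) were lower with CNT-2, and FTH1 was higher by 0.26 with overlapping arrays and with probes called in opposite directions, at −0.72 with spike-in centring. Of 26 cholesterol synthesis genes 8 were higher and 1 lower with CNT-2 (camera adjusted p = 0.0876), of 26 p53 targets 1 and 12 (0.0866), of 30 oxidative phosphorylation genes 2 and 11 (0.0992), of 21 sterol efflux genes 4 and 9 (0.105) and of 5 inflammasome genes 0 and 3 (0.147). For the other lists the camera adjusted p lay between 0.122 and 0.964, with a median and mean of different sign for inflammatory cytokines, matrix and apoptosis genes and a test opposite to the median or mean for interferon-stimulated and ribosomal protein genes.

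For CNT-2 against CNT-1 in A549, HMOX1 (−0.06, adjusted p = 0.755), CCL2 (−0.13, 0.476), PTGS2 (0.41, 0.144) and HMGCS1 (−0.17, 0.218) were not called. MT2A (0.05, adjusted p = 0.822) and CDKN1A (0.00, 0.982) were not called and turned negative with spike-in centring. In all, 7756 of 17658 genes were called, 3836 higher and 3920 lower with CNT-2, with 1127 higher and 220 lower by at least 2-fold, and the groups did not overlap for 39.3% of genes (2.86% by chance). Of the 1127, 822 (72.9%) had no plain gene symbol. Spike-in centring gave 14504 calls, 563 of them higher, and normexp background correction lowered the genes at 2-fold or more to 632 in place of 1347.

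**Figure D4:**
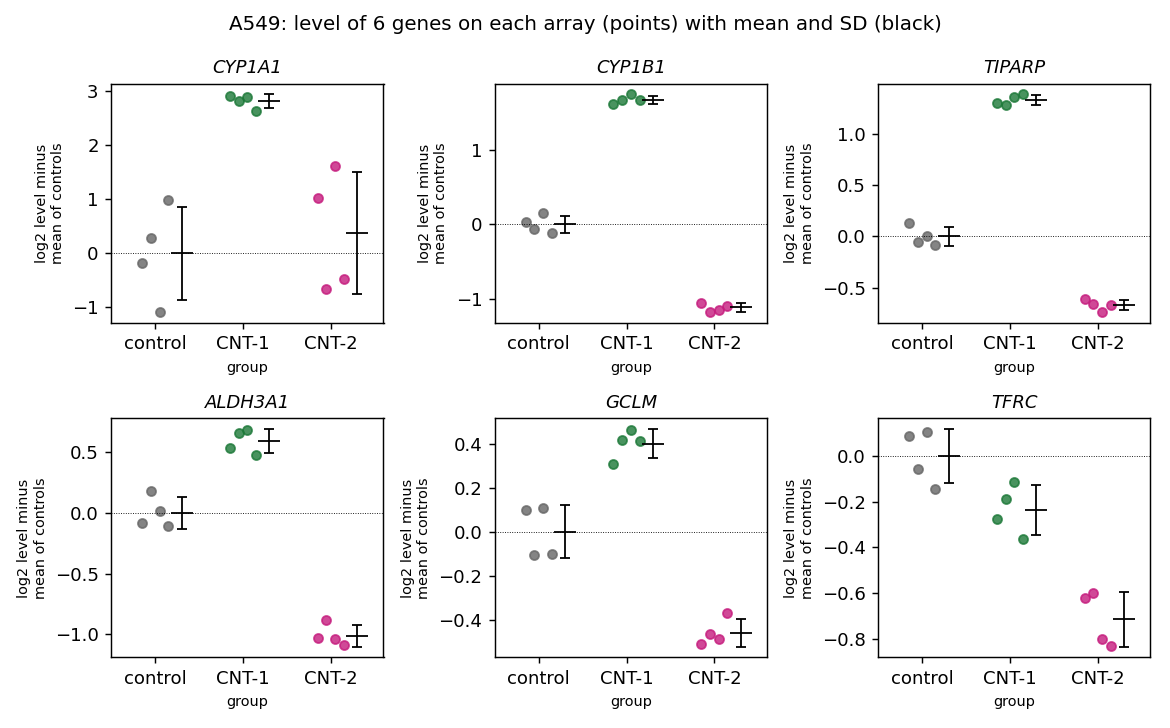
Levels of CYP1A1, CYP1B1, TIPARP, ALDH3A1, GCLM and TFRC on each A549 array (points, log2 level minus the mean of the controls) by group, with mean and SD of 4 arrays in black. CYP1A1 was above background only with CNT-1, CYP1B1 rose to 1.67 with CNT-1 and fell to −1.11 with CNT-2, and TFRC fell to −0.71 with CNT-2.

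Of 17658 genes in A549, 960 were called higher with both nanotubes (496 by chance), 322 lower with both (302 by chance) and 515 in opposite directions. Giving each nanotube its own 2 control arrays left a median of 354 shared calls, from 277 to 471, in place of 1282. The log2 differences correlated across genes with r = 0.14, where noise with shared controls alone gave a mean of 0.50, while their covariance was 0.0281, against 0.0135 in that noise, and genes are not independent replicates. Over the splits of the controls the covariance ran from 0.00015 to 0.0366 and r from 0.00065 to 0.18. The covariance thus leaves open whether the nanotubes shared a response in A549.

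The difference between the cell lines was tested directly on 7486 genes measured on both arrays. For CNT-1, 1685 genes differed in response, 1182 of them with the larger value in A549. For CNT-2, 2925 differed, 1747 with the larger value in A549. After scaling, the spike-in level of the A549 CNT-2 arrays lay 1.14 above control. The CNT-2 counts and differences in this paragraph are therefore relative to the other genes on the array and depend on the scaling. HMGCS1 responded less in A549 than in NR8383, by −0.65 for CNT-1 (adjusted p = 0.000528) and by −2.38 for CNT-2 (6.26e-12). TFRC responded to CNT-1 with a value higher in A549 by 1.51 (adjusted p = 8.59e-10), HMOX1 with one lower by −0.62 (0.00659) and NQO1 with one lower by −0.54 (7.8e-06). DDIT3 responded to CNT-2 with a value lower in A549 by −1.29 (adjusted p = 2.28e-07). The cholesterol list responded less in A549, with a median difference of −0.41 for CNT-1 (0.00118 with an estimated correlation) and −1.10 for CNT-2 (3.83e-05 with an estimated correlation). For the other lists that differed by camera, the adjusted p with an estimated correlation lay between 0.0931 and 0.671. Across genes, responses to CNT-1 in both lines correlated with r = 0.09 and those to CNT-2 with r = 0.03, and genes are not independent replicates. Genes called in the same direction in both lines numbered 254 for CNT-1 (190 by chance) and 427 for CNT-2 (399 by chance), and those in opposite directions 99 and 395.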

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

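Tests chosen after the result was seen are the 1 on slides for CNT-1 in A549, the 1 of CNT-2 against CNT-1 for the cholesterol genes, the 1 on slides for those genes, and those of single arrays or probes and of slower proliferation for Tfrc.

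In NR8383 with CNT-1, Tfrc fell by 1.74 ± 0.06 (SE, 4 arrays against 4), and with CNT-2 it was at −0.05 ± 0.06. A single array or probe as the source is argued against, since the highest CNT-1 array lay −1.524 from the lowest control array and all 3 Tfrc probes were lower, from 3.97 to 2.23, from 0.03 to −1.84 and from −2.70 to −4.50. Slower proliferation, which lowers the demand for iron, is argued against by the DNA replication list, whose median was 0.07617 and of whose 34 genes none fell. More iron in the cells would let iron regulatory proteins release both Tfrc and the form of Slc11a2 that carries their binding site. Slc11a2 stood at 0.1629 with CNT-1 (adjusted p = 0.0254), which argues against this reading as far as the probe reads that form, which was not determined. With CNT-2, where Tfrc was not called, Slc11a2 was at 0.2352 (adjusted p = 0.00148). Its rise therefore did not track the fall of Tfrc and is weak evidence on the cause of that fall. A response of the cells to CNT-1 by another route may explain the fall, and it stays open together with a difference between slides, since each group lay on 1 slide.

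In NR8383, genes of cholesterol synthesis and uptake rose with both nanotubes, with a median of 0.67 for CNT-1 and 1.70 for CNT-2. For the CNT-2 rise, a chance deviation of the shared control arrays as the only source is argued against by CNT-2 against CNT-1. That comparison uses no control array and gave a list median of 0.8291. For the CNT-1 rise, a deviation of some control arrays is argued against by CNT-1 against each pair of control arrays. The lowest list median over these pairs was 0.6556. A deviation common to all control arrays would stay in every pair, so it was not tested for CNT-1. A shortage of free sterol may raise these genes, and it would lower targets of the liver X receptor, which senses sterols. The median of 4 such targets with CNT-2 was −0.2179, from Abca1 at −0.80 and Abcg1 at −0.39 to Nr1h3 at −0.05 and Lpcat3 at 0.06, while Mylip, a further target added after its value was seen, was at −1.51, so members that moved by different amounts leave this open. A difference between slides stays open too, although the same list had a median of 0.4159 in A549 with CNT-2, on other slides and on arrays with a higher spike-in level.

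In A549 with CNT-1, 756 of the 959 genes lower by at least 2-fold had no plain gene symbol, and dim probes near background as the only source are argued against, since 42.02% of the genes lower by at least 2-fold had a control mean above that of the median gene. Genomic DNA or unspliced RNA labelled more weakly on these arrays could lower such transcripts, and it would lower pseudogenes below their parent genes. Pairs were matched by symbol, so some of the 122 were coding genes with look-alike names. The median of pseudogene minus parent with CNT-1 was −0.1623 over 122 pairs (bootstrap 95% interval −0.26 to −0.08, 79 pairs lower). With CNT-2 against control, where 152 genes were lower by at least 2-fold, it was −0.133 (−0.17 to −0.10, 85 of 122 pairs lower). With CNT-2 against CNT-1 it was 0.057 (−0.03 to 0.18, 53 of 122 pairs lower). In the 99 pairs without look-alike families, these medians were −0.162 (−0.27 to −0.06), −0.115 (−0.15 to −0.07) and 0.15 (−0.004 to 0.23). An offset from control was thus present with CNT-2 too, but whether it was larger with CNT-1 was not settled. Both offsets use the same control arrays, so they are not independent of each other. The intervals measure spread over pairs, some of which share a parent gene, and not spread over arrays or slides. Weaker labelling stays open, also because pseudogenes already seen among the largest changes were left out of these pairs. A response of the cells to CNT-1 cannot be told apart from a difference between slides, since each group had 1 slide.

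In A549 with CNT-2 the E1A spike-in probes, which do not measure genes of the cells, lay 1.139 above control on average (0.67 to 1.96 over the 4 arrays). No explanation was tested for it.

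Arrays far from the other 3 of their group, relative to the range of the group, came up in 7 of 105 groups, where chance gives 5.25, about 1 in 20. The log2 level of Tnf on NR8383 control array 2 was −2.629 (others −2.49 to −2.48), that of Srxn1 on NR8383 CNT-2 array 3 was −1.48 (others −1.38 to −1.36) and that of Hmgcs1 on the same array was 3.708 (others 3.62 to 3.64). The level of SRXN1 on A549 control array 1 was 5.341 (others 5.30 to 5.31), that of CDKN1A on A549 control array 2 was 1.39 (others 1.19 to 1.22) and that of HMGCS1 on A549 CNT-2 array 4 was 0.717 (others 1.01 to 1.02). On A549 control array 4, 0.3435% of spots were set missing (others 0.148 to 0.164%).

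Responses that differed between the cell lines by the test of the difference itself are given as the log2 response in A549 minus that in NR8383. For CNT-1 these were TFRC at 1.507, CDKN1A at 0.2578, HMGCS1 at −0.6454, HMOX1 at −0.6226, NQO1 at −0.5429 and SRXN1 at −0.2488. For CNT-2 they were HMGCS1 at −2.379, DDIT3 at −1.289, TFRC at −0.6694, CCL2 at −0.4188 and SRXN1 at −0.405. These CNT-2 values, and the CNT-2 list medians below, depend on the scaling, since the A549 CNT-2 arrays had a higher spike-in level. Of the lists, the median difference for CNT-1 was 0.619 for inflammasome and pyroptosis, 0.3246 for sterol efflux and lipid storage, 0.2957 for glycolysis, −0.039 for lysosome and −0.4143 for cholesterol synthesis and uptake. For CNT-2 it was −1.097 for cholesterol synthesis and uptake, −0.5367 for aryl hydrocarbon receptor targets, −0.5219 for fatty acid synthesis, −0.2833 for NF-kB feedback and targets, −0.2171 for lysosome, −0.1499 for the unfolded protein and integrated stress response, 0.2063 for DNA replication and 0.2235 for cytosolic ribosomal proteins. The receptor list rested on 4 genes measured on both arrays, and CYP1A1, CYP1B1 and TIPARP were not among them. Except for the cholesterol list, none of these lists differed when tested with an estimated correlation (adjusted p from 0.0931 to 0.671).

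For all 12 counts of genes within a cell line, only 1 of 35 splits reached the count, the real one. This is the lowest share that 35 splits allow, and it makes a random division of the arrays an unlikely source. Because each group lay on 1 slide, a slide offset could also put the real split first, so the splits cannot tell it from a response. Genes called in NR8383 numbered 3308 for CNT-1 against control (highest other split 0), 6929 for CNT-2 against control (58) and 5781 for CNT-2 against CNT-1 (5), and those at 2-fold or more 85 (0), 489 (1) and 347 (2). In A549 the genes called numbered 5767 (465), 4811 (0) and 7756 (0), and those at 2-fold or more 977 (108), 232 (0) and 1347 (0). For the difference between the cell lines, 1 of 100 splits, the real one, reached 1685 genes for CNT-1 (highest other 1337). For CNT-2, 1 of 100 reached 2925 (highest other 1405). The other draws could keep the real groups in 1 of the cell lines, and the limit set by the slides holds here too.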

How the results depend on the processing

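Alternatives chosen after the data were seen are spike-in centring, plain symbols only, and leaving out arrays in the list tests and in the difference between cell lines. A slide block could not be fitted and was not run, because each group had 1 slide, and the array number as a block pairs no arrays consistently, since an array's own number was its best match for 0 to 2 of 4 arrays in each pair of groups (r across genes from −0.30 to 0.54). With 4 arrays per group and a median SD of 0.09 log2 units in NR8383 and 0.15 in A549, small differences are limited by the number of arrays, and probes near background by the signal. Without leaving out arrays, 4543 values of named genes stayed the same, 248 lost the call, 30 gained one and 23 changed sign. Staying the same meant keeping the direction and the side of the threshold. The 4543 include values of the deposited value table, which has no p-value. Those counted as the same when they lay within 1 SD between arrays of the main value, so no call was tested for them. For list tests 148 kept their call, 79 lost it and 1 changed direction, and for counts 134 stayed within 1.5 times and 52 did not. Where arrays were left out, 4366 gene values kept their call, 161 lost it and 9 gained one, and 651 list tests kept theirs and 33 lost it.

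With normexp background correction, whose offset shrinks differences of dim probes, genes at 2-fold or more numbered 14, 224 and 118 in NR8383 (CNT-1, CNT-2 and CNT-2 against CNT-1) and 498, 57 and 632 in A549, genes called in A549 2979, 1767 and 4284, and TMEM47 in A549 CNT-2 against control was at 0.02548. Without the filter, which adds dim probes to the tests, 1427 genes were called for CNT-1 and 3538 for CNT-2 against CNT-1 in NR8383, and 3027 for CNT-2 in A549. With the stricter filter, which tests fewer genes, 30 and 217 genes in these NR8383 comparisons and 134 for CNT-2 in A549 were at 2-fold or more. With plain symbols only, again fewer genes, 1988, 3517 and 3251 were called in NR8383 and 3735 for CNT-1 in A549, and 45, 99 and 69 in NR8383 and 218, 104 and 430 in A549 were at 2-fold or more. Array weights gave 9285 genes called for CNT-1 in A549, and the cause was not tested.

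Spike-in centring gave 753, 3937 and 2096 genes called in NR8383 and 1273, 16850 and 14504 in A549, with 11221 for CNT-2 and 9007 for CNT-2 against CNT-1 at 2-fold or more, because it moves all genes of an array by the spike-in level, and 6, 1 and 2 lists in A549. It changed the sign in A549 CNT-2 against control of MT2A (−1.078), FTH1 (−0.9923), PTGS2 (−0.9746), HMGCS1 (−1.099), CDKN1A (−0.9978), TM7SF2 (−0.4309), ACAT2 (−0.5431), FDPS (−0.546), RPL32 (−0.7154), RPS24 (−0.7349), RPL28 (−0.7635) and RPS2 (−0.7805). Against CNT-1 it did so for MT2A (−0.9348), FTH1 (−0.7226), CDKN1A (−0.9833), CX3CL1 (−0.1815), CXCL3 (−0.2955), CXCL16 (−0.6827), UBE2C (−0.4668) and PSMD3 (−0.271).

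Lists passing with an estimated correlation numbered 3, 1 and 4 in NR8383 and 0 for CNT-1 and 0 for CNT-2 against CNT-1 in A549 (7 and 6 at an unadjusted p under 0.05), and with fry, which asks another question, 25, 22 and 27 in NR8383 and 22, 11 and 22 in A549. Quantile normalization gave 0 lists for CNT-1 and 7 for CNT-2 in A549, with the list of cytosolic ribosomal proteins for CNT-2 in the opposite direction (adjusted p = 0.798), and the cause was not tested. With the mean of a gene's probes, CDKN1A was at −0.2952 and PFKFB3 at 0.1398 in A549 CNT-2 against CNT-1. Splitting the controls left 1054 shared calls in NR8383 and 354 in A549, with fewer control arrays per nanotube.

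Leaving out 1 array gave 2186 to 3324 genes called for CNT-1 in NR8383 (lowest without control array 2) and 3080 to 5229 for CNT-2 in A549 (lowest without control array 1). Genes at 2-fold or more for CNT-2 in A549 numbered 143 to 352 (lowest without CNT-2 array 4, highest without CNT-2 array 1). Lists passing camera in A549 numbered 7 to 12 for CNT-1 (lowest without CNT-1 array 2) and 3 to 7 for CNT-2 (highest without CNT-2 array 4).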

Other observations

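The values named here were chosen after they were seen, and no explanation of them was tested.

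In NR8383, Tfrc was called with CNT-1 only, while some other iron genes were called with both nanotubes in the same direction. The iron carrier transferrin, Tf, was at −0.56 with CNT-1 and −0.51 with CNT-2, and the phagosomal metal transporter Slc11a1 at 0.56 and 0.58. The ferritinophagy receptor Ncoa4 was at 0.29 and 0.26, the iron sensor Fbxl5 at 0.28 and 0.17, and Slc11a2 at 0.16 and 0.24. Of these, Fbxl5 differed between the nanotubes (adjusted p = 0.0447). Called with CNT-2 only were the iron genes Ireb2, at 0.32 (adjusted p = 0.00124), and Slc25a28, at −0.20 (0.036). Both also differed between the nanotubes (adjusted p = 0.0268 and 0.0326). In the same cells the ubiquitin ligase gene Mylip was at −0.58 with CNT-1 and −1.51 with CNT-2, and the sterol exporter Abca1 at −0.40 and −0.80.

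The gene for the regulator of the NRF2 targets, Nfe2l2, was at −0.11 (adjusted p = 0.178) in NR8383 with CNT-1, where the list of NRF2 targets rose, and at 0.41 (0.000117) with CNT-2, where that list did not pass. In A549, NFE2L2 was at 0.15 (adjusted p = 0.0927) with CNT-1 and at −0.35 (0.00367) with CNT-2.

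Multi-probe genes with probes called in opposite directions numbered 4, 80 and 56 of 3065 in NR8383 (CNT-1, CNT-2 and CNT-2 against CNT-1) and 164, 231 and 543 of 5260 in A549. In the deposited value table, the column of NR8383 with CNT-1 follows the mean of arrays 2 to 4, while the report uses all 4 arrays.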
